A study of Mus musculus with 8 samples.

How the data were processed

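The data were ChIP-seq peak lists of 5 libraries from mouse embryonic stem cells of the TT2 line, 1 list per library. The series also has 3 input libraries, which were not analysed here. Samples were grouped by their titles: Ezh2 in wild-type cells (2 libraries, numbered 0 and 1), Ezh2 in cells lacking G9a and GLP (1, numbered 0), G9a in wild-type cells (1) and G9a in knockout cells rescued with wild-type G9a (1). For the knockout Ezh2 library the title and description name the knockout, while its source name gives the cell line alone; the title was followed. Peak lists carry no measure of G9a or GLP in the cells, so the knockout could not be checked from them. Nothing in the labels says that the wild-type Ezh2 libraries came from separate cultures, so their spread may be technical.

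Cells were fixed with 1% formaldehyde for 10 min, per the labels' protocols. The G9a samples were first fixed with 2 mM DSG, a protein crosslinker, for 45 min. Libraries were amplified with 15 PCR cycles. Bowtie 0.12.7, MACS 1.4 and the mm9 genome build are named in the submitters' processing notes. Per the series' design text, the authors pooled the wild-type inputs as the control for the Ezh2 and G9a samples; whether the knockout and rescue lists used another control is not stated. The deposited lists give each peak's chromosome, start and end and a score made by the authors' peak caller, defined by MACS as 10 times the negative log10 of the peak's p. The call threshold is not given in the sources used here; the lowest scores, 43.02, 30, 43.03, 20 and 20 in wild-type Ezh2 0 and 1, knockout Ezh2, wild-type G9a and rescue G9a, correspond to p of 4.99e-05, 0.001, 4.98e-05, 0.01 and 0.01. Scores are the authors' own values, and were used to rank or filter peaks within a list. Some alternatives used the same minimum score for several lists, whose score scales may differ. The lists hold no read counts, so the depth is unknown and no interval for counting reads was given. Positions are printed 1-based on mm9.

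All peaks on chromosomes 1 to 19, X and Y were used. A peak was counted as found in another list when it overlapped a peak there by at least 1 bp. Overlapping peaks of the 3 Ezh2 lists were merged into regions. A region was kept when it held peaks of both wild-type libraries and of the knockout, missing when it held both wild-type libraries only, and knockout-only when it held knockout peaks alone. The 95% intervals came from 2000 resamples of 10 Mb blocks of the genome, because neighbouring peaks are not independent. The Ezh2 and G9a overlap was compared with 1000 random placements of the Ezh2 regions on their own chromosomes in a one-sided permutation test. It describes these lists and not variation between replicates. Positions were drawn evenly along the chromosome length and were not matched for where peaks can be called. For single region classes 200 placements were used, and for pairs of lists 20. The odds ratio of being kept was a Cochran-Mantel-Haenszel estimate over 10 groups of regions of equal size by library 0 score. Each group except wild-type Ezh2 had 1 library, so no test between conditions was run.

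Computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9. Chromosome lengths of mm9 came from GenomeInfoDb 1.38.1. The procedures were tested on simulated data. A planted share of 60% of 5425 Ezh2 peaks was recovered as 60%, and randomly placed peaks gave a mean fold of 0.989. A planted odds ratio of 0.5 over 2642 regions was recovered with a median of 0.502, and 47 of 50 intervals held it. These draws were independent between regions, so they did not test the intervals under dependence between neighbouring regions.

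The tests, the groups, the naming rule and most alternatives were chosen before the data were examined. The alternatives were a stricter overlap, a gap of up to 1 kb, scores of at least 100, equal list lengths, merging of peaks within 1 kb, leaving out each wild-type Ezh2 library, rescue or shared G9a peaks, placements within 1 Mb, and other matching for the odds ratio. A common lowest score of 43.03 for the Ezh2 lists, leaving out chromosome X or chromosomes 1 and 8, knockout Ezh2 peaks in place of wild-type regions, a minimum score for G9a peaks alone, and matching by score and width together were chosen after seeing the data. The naming rule asked for genes with promoter peaks where an annotation of the mm9 build was given, and otherwise for the first 5 regions of each class by position. No mm9 annotation was used here, so regions were named by position, taking the first 5 of each class in the rule's order of mean rank of peak score within the lists. For the same reason the tests of gene lists at promoters were not run, and no gene was assigned to a peak.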

Results

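Chromatin occupancy of Ezh2 and G9a was measured by ChIP-seq in TT2 mouse embryonic stem cells. Ezh2 is the catalytic subunit of Polycomb repressive complex 2, which methylates lysine 27 of histone H3 (H3K27). G9a and its partner GLP methylate lysine 9 of histone H3 (H3K9). Ezh2 was profiled in 2 wild-type libraries, which the labels number 0 and 1, and in 1 library from cells lacking both G9a and GLP. G9a was profiled in 1 wild-type library and in 1 library from knockout cells given back G9a, called the rescue. The rescue title names G9a alone as put back, so these cells still lacked GLP by their label. The wild-type Ezh2 lists held 5425 peaks (library 0) and 11766 peaks (library 1), and the knockout Ezh2 list held 6198. The G9a lists held 67318 peaks in the wild type and 83721 in the rescue. These Ezh2 peaks covered 4.03, 15.0 and 3.38 Mb of the mm9 genome, and the G9a peaks covered 53.6 and 46.7 Mb. The lists give peaks and not read counts, so the depth of each library is unknown. Their lowest scores also differed: 43.02 and 30 in wild-type Ezh2 libraries 0 and 1, 43.03 in the knockout, and 20 in both G9a lists.

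The wild-type Ezh2 libraries give the spread against which the knockout is read. Library 1 held almost all of the Ezh2 sites of library 0 and many more besides. Of the library 0 peaks, 91.3% (4951 of 5425; 95% interval 89.9 to 92.5) overlapped a library 1 peak, against 0.949% at random positions. Of the library 1 peaks, 22.5% (2648 of 11766; 21.5 to 23.5) overlapped a library 0 peak. The strongest sites were shared: 98.6% of the top 10% of library 1 peaks by score were found in library 0, and 1.10% of the lowest 10% were. Merged over the 3 Ezh2 lists, the peaks formed 13994 regions, of which 2642 held peaks of both wild-type libraries. The intervals come from resampling 10 Mb blocks, so they cover variation along the genome and not variation between cultures.

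The next comparison asks whether Ezh2 stays at its sites in cells without G9a and GLP. Most regions held by Ezh2 in both wild-type libraries were still called in the knockout. Of these 2642 regions, 1653 (62.6%; 95% interval 60.5 to 64.7) held a knockout peak and 989 (37.4%) did not. Strong regions were kept more often: 263 of the 264 in the top 10% of library 0 score held a knockout peak, against 29.4% in the lowest 10%. Ranked by library 1 score the values were 264 of 264 and 13.2%. Among all library 1 peaks, whether or not library 0 had them, 89.97% of the top 10% (87.9 to 91.9) were found in the knockout, against 98.6% in library 0. Regions missing from the knockout list had a median library 0 score of 67.57, against 230.88 in kept regions. Within kept regions, knockout peaks covered a median of 928 bp, against 1239 bp for library 0 and 2985 bp for library 1.

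**Figure D1:**
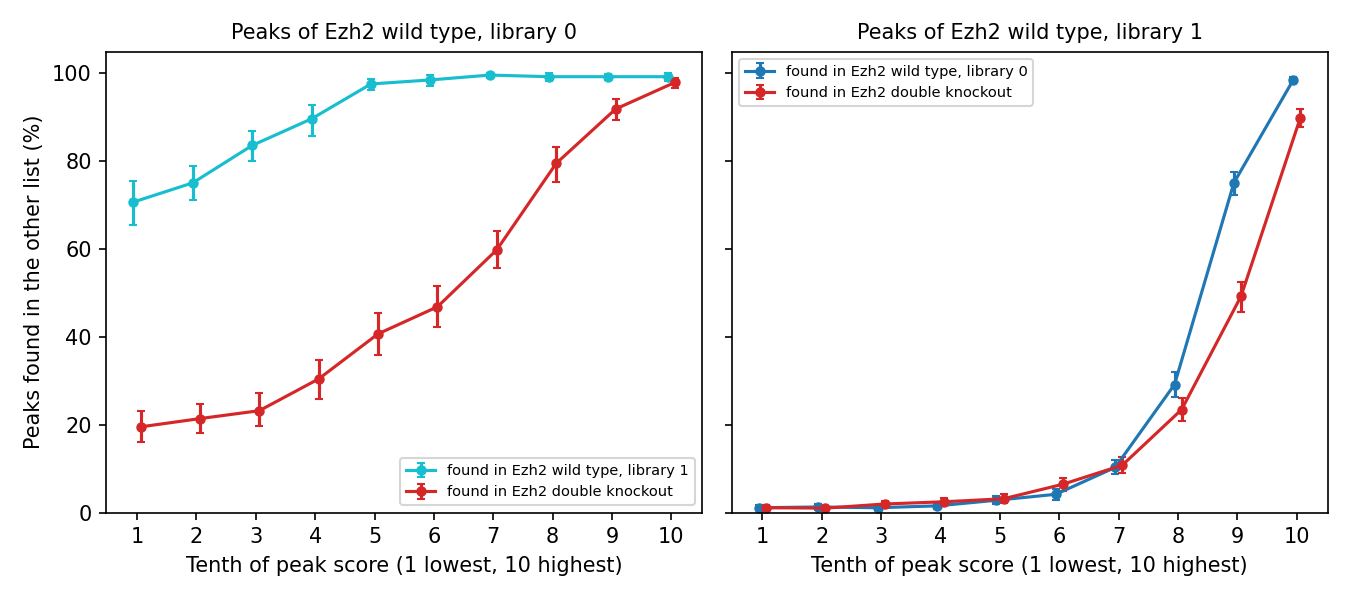
Percent of wild-type Ezh2 peaks that overlap a peak of another Ezh2 list, over 10 groups of equal size by peak score (1 lowest, 10 highest), for library 0 (left) and library 1 (right), with 95% intervals from 10 Mb blocks. In the lowest group of library 0, 70.7% of peaks were found in library 1 and 19.5% in the knockout; in its top group the values were 99.3% and 98.0%.

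How far the knockout stood from the wild type depended on the wild-type library it was set against. Library 0 peaks were found in the knockout list in 51.1% of cases (48.9 to 53.3), 40.1 points fewer (38.0 to 42.2) than in library 1. Library 1 peaks were found in the knockout list in 18.96% of cases (18.0 to 19.9), 3.54 points fewer (2.63 to 4.44) than in library 0. This difference averages over many weak library 1 peaks that were seldom found in either list. Over the 10 groups by score, the shares in library 0 and the knockout were close up to group 7 (10.3% and 10.8%). They were 29.2% and 23.5% in group 8, and 75.1% (72.4 to 77.6) and 49.3% (45.8 to 52.5) in group 9. Of the knockout peaks, 71.0% (68.5 to 73.3) lay in library 1 and 52.5% (50.0 to 55.1) in library 0. In kept regions the knockout peaks covered less than those of either wild-type library, with median ratios of 0.796 (0.771 to 0.827) to library 0 and 0.343 (0.325 to 0.358) to library 1. The ratio of library 0 to library 1 was 0.464 (0.447 to 0.476). With equal numbers of top-scoring peaks, 46.8% of library 1 peaks lay in library 0 and 36.8% in the knockout, a difference of 9.99 points (8.30 to 11.7). With 1 knockout library there is no test between the conditions. The kept share rests on requiring both wild-type libraries: it was 18.8% of regions without library 0 and 46.9% without library 1, with 9535 and 2651 regions missing from the knockout.

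The highest-ranked regions of each class are named by their mm9 positions. The region on chromosome 11 from 84327169 to 84344787 ranked first among those in all 3 Ezh2 lists, with highest peak scores of 3100 in both wild-type libraries and 2986.07 in the knockout. It was followed by chromosome 11 from 21891493 to 21901777 (knockout score 2660.28), chromosome 5 from 33771182 to 33780011 (2086.83), chromosome 11 from 98179559 to 98192891 (1974.35) and chromosome 12 from 57627085 to 57639454 (1757.08). Among regions missing from the knockout list, chromosome 1 from 39248626 to 39252656 ranked first, with scores of 821.53 in library 0 and 2695.16 in library 1. The next were chromosome 11 from 75005533 to 75009764 (library 0 score 619.48), chromosome 13 from 51942020 to 51944118 (639.43), chromosome 5 from 4754918 to 4759097 (582.39) and chromosome 12 from 84825503 to 84828591 (532.54). Scores rank peaks within a list, so those of these regions were not compared between lists.

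Ezh2 was also called at sites of the knockout where neither wild-type library had a peak. There were 1776 such regions, against 450 found in library 0 alone and 8543 in library 1 alone. They were short, with a median span of 293 bp, against 2992 bp for regions in all 3 lists. Regions of 1 wild-type list alone were short too, at 286 bp for library 0 and 555 bp for library 1. The highest-scoring were on chromosome 3 from 105261558 to 105262664 (score 192.25), chromosome 17 from 16286852 to 16287264 (178.58) and chromosome 11 from 95063110 to 95063879 (163.28). Next came chromosome 4 from 118221111 to 118221391 (142.78) and chromosome 8 from 107802707 to 107803620 (130.02). Chromosomes 8 and 11, chosen after their values were seen, carried 27.8% of the knockout-only regions (494), against 13.7% of the regions in both wild-type libraries and 9.55% of the genome length. They also carried 16.4% of all library 1 peaks and 14.2% of library 0 peaks, and the difference was not tested. Most knockout-only calls were weak, with a median score of 47.33 and 10 of the 1776 at 100 or more. With a minimum score of 100 in every list the count was 24, of which 10 lay in the regions counted above, and without library 1 it was 2944.

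Coverage by knockout peaks was also compared in the 3 longest kept regions, chosen after their values were seen. Kept regions hold a knockout peak by definition, so only the covered length is informative. Each was a single peak in wild-type library 1. The longest ran from 96129021 to 96219132 on chromosome 11 (90112 bp) and held 53 peaks of library 0 covering 60348 bp and 57 knockout peaks covering 58848 bp. The region on chromosome 6 from 52145250 to 52205340 was covered over 40756 bp in library 0 and 35019 bp in the knockout. The region on chromosome 2 from 74511324 to 74543344 was covered over 20043 bp and 13912 bp. The wild-type G9a list had 2, 1 and 0 peaks in these regions, in that order.

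**Figure D2:**
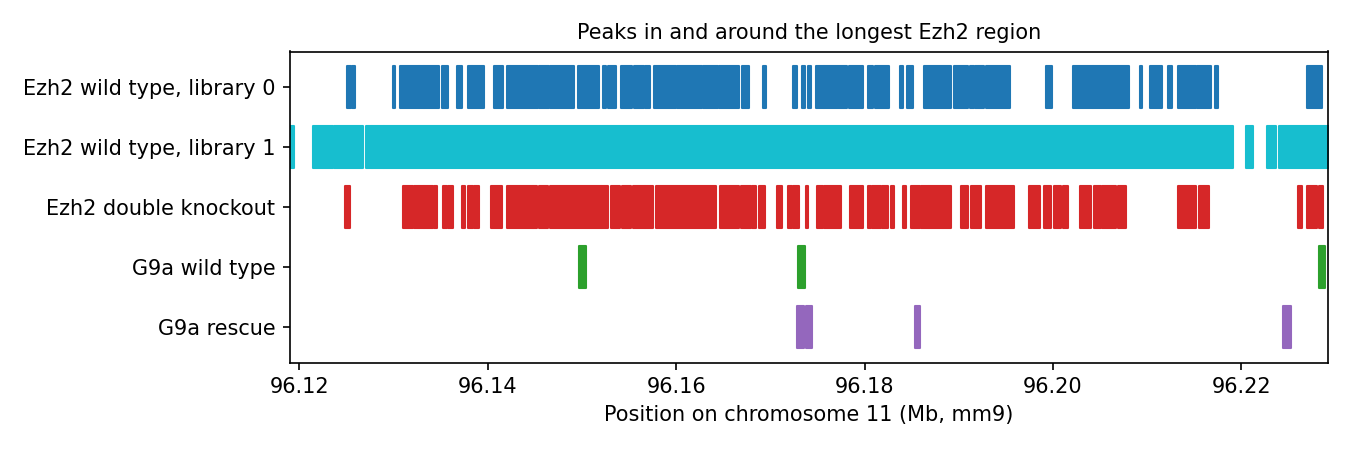
Called peaks in and around the longest kept Ezh2 region, on chromosome 11 (position in Mb, mm9, with 10 kb added on either side). Each block is 1 peak, with 1 track per list. The window holds 56 peaks of wild-type Ezh2 library 0, 9 of library 1 and 61 of the knockout, with 3 G9a peaks in the wild type and 4 in the rescue.

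Chromosome X stood apart from the autosomes in the knockout Ezh2 list. The wild-type Ezh2 libraries had 83 and 172 peaks on chromosome X and the knockout had 21. Of the 50 regions of X held by both wild-type libraries, 10 were called in the knockout (20.0%; exact binomial 95% interval 10.0 to 33.7). On the autosomes 1643 of 2592 were called (63.4%; 61.3 to 65.5).

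The G9a libraries ask whether G9a put back into knockout cells, which by their label still lacked GLP, occupies the wild-type sites. Differences between these lists cannot be told apart from an effect of the missing GLP. Rescue G9a lay at wild-type G9a sites far more often than random positions would, but most peaks of each list were absent from the other. Of the wild-type peaks, 31.9% (21446; 95% interval 30.0 to 33.7) overlapped a rescue peak, 7.53-fold above random positions. Of the rescue peaks, 27.2% (22774; 25.9 to 28.5) overlapped a wild-type peak. Strong peaks were shared most: 75.9% of the top 10% of wild-type peaks were found in the rescue, against 13.7% of the lowest 10%. The highest-ranked shared region, on chromosome 4 from 150977827 to 150981044, had scores of 3100 in the wild type and 3201.3 in the rescue. It was followed by chromosome 19 from 4985666 to 4990798 (wild-type score 2114.11), chromosome 18 from 25825409 to 25828041 (1903.18), chromosome 15 from 72398089 to 72400165 (1603.24) and chromosome 4 from 139813675 to 139816366 (1465.54). Of these 5 regions, the one on chromosome 19 held an Ezh2 peak, in wild-type library 1. With 1 library in each group there is no test between them. When only peaks with a score of at least 100 were used in both lists, the shared share of wild-type peaks was 18.5%, with 7214 wild-type and 3059 rescue peaks left.

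G9a peaks were spread over the chromosomes differently in the 2 lists. Chromosome 1 had 8226 wild-type and 2262 rescue peaks, and chromosome 8 had 5186 and 1354. Together they carried 19.9% of wild-type and 4.32% of rescue peaks, with 12.4% of the genome length. Chromosomes 6 and 13 had 9.46% of wild-type and 16.3% of rescue peaks on 10.2% of the length, and a single 10 Mb block of each carried most of this excess. The block starting at 120 Mb on chromosome 6 had 458 wild-type and 2475 rescue peaks, and the block starting at 110 Mb on chromosome 13 had 312 and 2108. Without these blocks, chosen after their values were seen, the rescue to wild-type ratios were 1.69 and 1.54, near the median of 1.47 for blocks of autosomes other than 1 and 8. The end of chromosome 11 had few rescue peaks, with 544 wild-type and 94 rescue peaks in the block starting at 110 Mb and 60 and 9 in the block starting at 120 Mb. On chromosomes 1 and 8, 12.2% of the wild-type peaks of each overlapped a rescue peak, against 32.8% to 44.5% on the other autosomes.

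**Figure D3:**
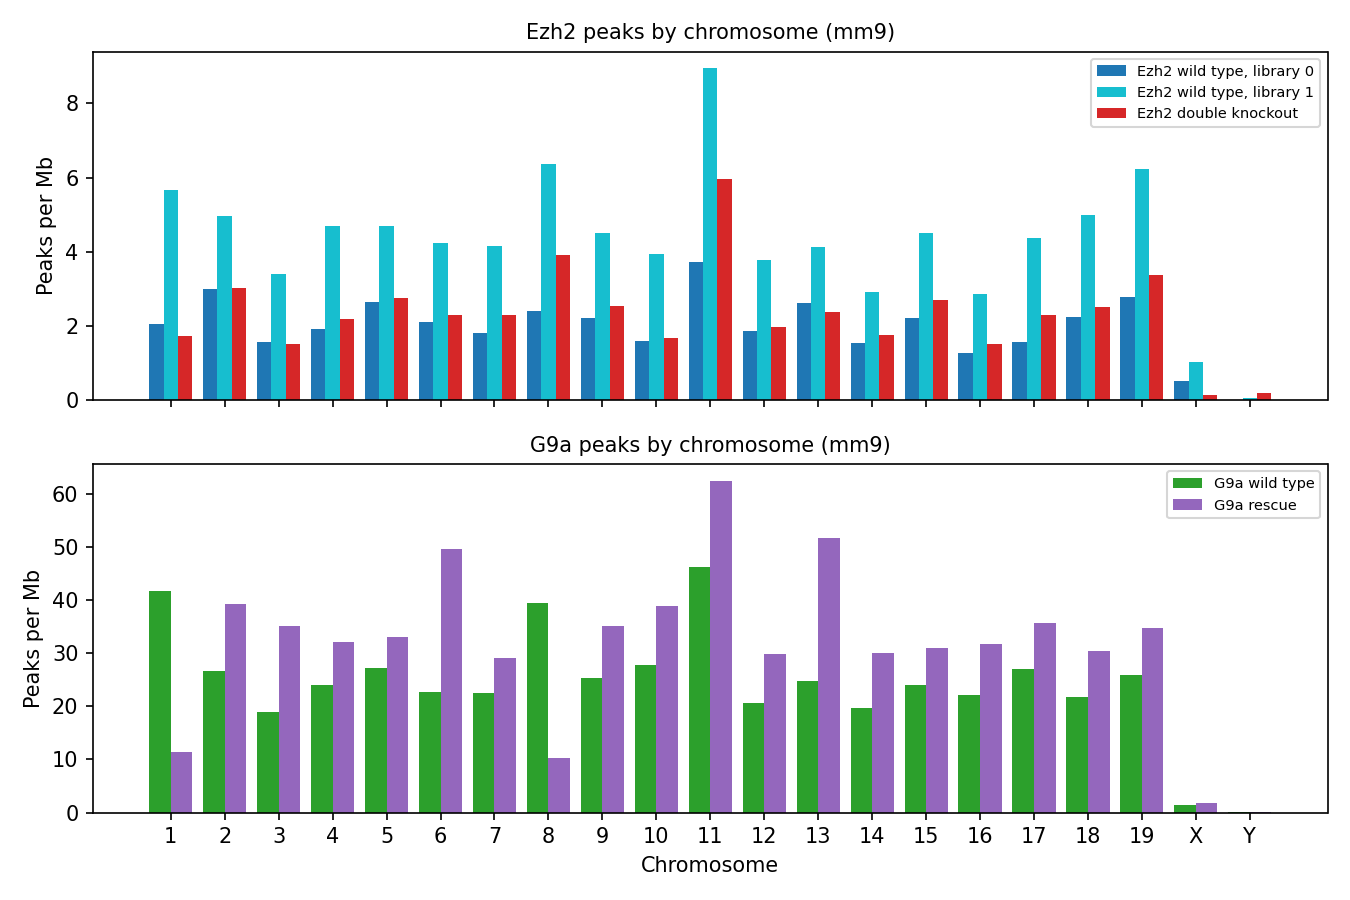
Peaks per Mb on each mm9 chromosome for the 3 Ezh2 lists (top) and the G9a lists (bottom); each bar is 1 library. Wild-type G9a peaks reached 41.7 per Mb on chromosome 1 and 39.4 on chromosome 8, against 11.5 and 10.3 in the rescue.

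Ezh2 and G9a peaks were then compared to ask whether the H3K27 and H3K9 methyltransferases occupy the same sites. Most Ezh2 regions held no called G9a peak, but more did than random positions would give. Of the 2642 Ezh2 regions of both wild-type libraries, 424 (16.0%; 14.6 to 17.4) held a wild-type G9a peak, against a mean of 231.585 (8.77%) for the same regions at random positions on their chromosomes. This was 1.83-fold, and none of the 1000 placements exceeded 270 (one-sided permutation p = 0.000999, the smallest they can give). Random positions were not matched for where peaks can be called, so the excess may not be particular to these 2 proteins. Rescue G9a peaks lay in 528 of the regions (20.0%), 2.02-fold above random positions. Against positions within 1 Mb of each region, the wild-type G9a value was 1.41-fold. Ezh2 regions called only in library 1 held wild-type G9a peaks in 13.6% of cases, 3.18-fold above random positions, library 0-only regions in 6.22% (1.67-fold) and knockout-only regions in 5.24% (1.503-fold). Over all peaks the overlap with wild-type G9a was 2.62-fold for Ezh2 library 1, 1.41-fold for library 0 and 1.39-fold for the knockout. The labels give both G9a libraries the number 1, as for Ezh2 library 1, and do not say whether the number marks a batch. With G9a peaks held to scores of at least 100 the overlap was 1.35-fold (49 regions; one-sided permutation p = 0.0240). With that minimum in every list it was 1.18-fold (30 regions; one-sided permutation p = 0.194), and with equal numbers of top-scoring peaks it was 1.16-fold (32 regions; one-sided permutation p = 0.216). Pooled wild-type inputs served as control for both proteins, per the series' design text, so the lists are not independent of each other.

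**Figure D4:**
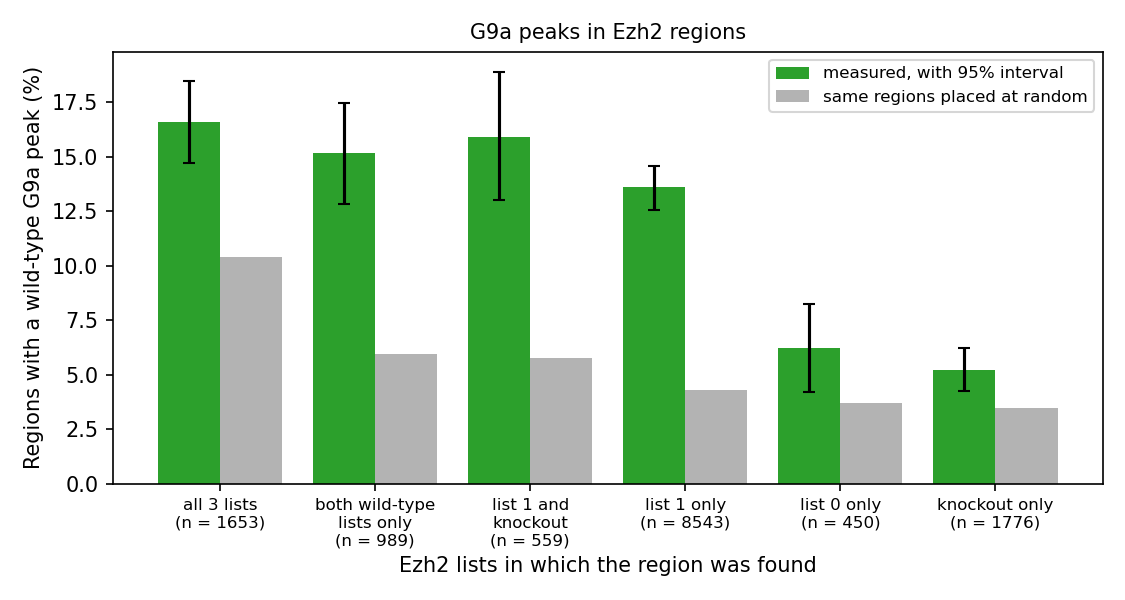
Percent of Ezh2 regions with a wild-type G9a peak (green, with 95% intervals from 10 Mb blocks) and the mean for the same regions at random positions (grey), by the Ezh2 lists in which the region was found. Regions in all 3 lists reached 16.6% against 10.4% at random, and regions in both wild-type lists but not the knockout reached 15.2% against 5.94%.

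Regions shared by both proteins led to the last comparison, whether Ezh2 was kept less often where a G9a peak was called. The series has no G9a library from knockout cells, so the background of the G9a calls is unknown. Before matching, Ezh2 regions with and without a G9a peak were kept at similar rates in the knockout. Of the 424 regions with a wild-type G9a peak, 274 (64.6%) were kept, against 1379 of 2218 (62.2%) without one. At matched library 0 score, the odds ratio of being kept with against without G9a was 1.08 (95% interval 0.835 to 1.41). With the rescue G9a peaks it was 1.18 (0.939 to 1.504). The highest-ranked shared regions were on chromosome 5 from 33771182 to 33780011, with a wild-type G9a score of 395.81, and on chromosome 11 from 98179559 to 98192891 (214.16). The others were on chromosome 8 from 80956315 to 80962381 (186.21) and on chromosome 18 from 77091518 to 77100088 (135.55) and from 42553444 to 42562280 (160.23). The odds ratio depended on the matching: at matched region width it was 0.720 (0.554 to 0.929), below 1. With score and width matched together it was 0.831 (0.635 to 1.09). Width went with both traits. From the narrowest to the widest 10% of regions, the kept share rose from 14.3% to 98.9% and the share with a G9a peak from 9.06% to 22.0%. Library 0 score went with being kept but little with G9a. Its lowest 10% had 39 regions with a G9a peak among 265, and its top 10% had 45 among 264.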

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

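The alternatives with a common lowest score, without chromosome X, without chromosomes 1 and 8, with knockout Ezh2 peaks, with a minimum score for G9a alone, and matched by score and width together were chosen after seeing the data. With scores of at least 100, the share of library 0 Ezh2 peaks found in library 1 moved from 91.3% to 97.6%, kept regions from 62.6% to 54.5%, knockout-only regions from 1776 to 24, and wild-type G9a peaks found in the rescue from 31.9% to 18.5%. The Ezh2 and G9a overlap fell from 1.83-fold to 1.18-fold (30 regions; one-sided permutation p = 0.194) and was no longer past 0.05. With equal list lengths the overlap was 1.16-fold (32 regions; one-sided permutation p = 0.216), replicate agreement was 89.3%, G9a agreement 29.4% and the odds ratio of being kept 0.905. In the overlap these settings leave 7214 and 5425 wild-type G9a peaks, so fewer regions entered it; the G9a agreement at equal lengths used 67318 peaks of each list. A gap of up to 1 kb gave 66.4% kept, 43.2% G9a agreement and an odds ratio of 0.871. Merging peaks within 1 kb gave 84.8% replicate agreement, 66.1% kept and an odds ratio of 0.929. Overlap of the greater part of the shorter peak gave a G9a agreement of 28.6%, and leaving out chromosomes 1 and 8 gave 36.8%. Leaving out each wild-type Ezh2 library in turn gave 18.8% to 46.9% kept, 2651 to 9535 missing regions, 1800 to 2944 knockout-only regions and odds ratios of 0.981 to 0.985. The odds ratio was 0.720 matched by width and 0.831 matched by score and width together. In all, 7 of its 16 alternatives lay on the other side of 1, with intervals that spanned 1 except when matched by width. The cause of these shifts was otherwise not tested. The overlap kept its direction in all 16 alternatives (1.16 to 2.66-fold) and its side of 0.05 in 14. Using all sequences named in the files changed nothing, because they hold chromosomes 1 to 19, X and Y alone. The highest-ranked named regions stayed in their class in all 7 alternatives, except that 3 of 5 knockout-only regions did with a 1 kb gap and 4 of 5 with peaks within 1 kb merged. The alternatives for promoter windows and gene lists were not run, since no mm9 annotation was used here. No paired analysis was possible because the input libraries have no peak list used here and the knockout has 1 library, so the compared groups share fewer than 2 label numbers. Depth is unknown, so a site absent from a list is one that was not called there, not one shown to be unbound.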

Other observations

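Ezh2 regions called only in wild-type library 1 were the largest class, with 8543 of the 13994 regions. They held wild-type G9a peaks in 1161 cases (13.6%) and were short, with a median span of 555 bp. Ezh2 regions shared by library 1 and the knockout (559) held wild-type G9a in 15.9% of cases, 2.77-fold above random positions. Knockout-only Ezh2 regions reached 1.82 per Mb on chromosome 8 and 2.08 per Mb on chromosome 11, against 0.382 to 0.897 per Mb on the other autosomes.

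Among the tests below, that of list length for G9a, that of low signal along X and both tests of Ezh2 regions with low scores were chosen only after the result was seen. G9a peaks on chromosomes 1 and 8 were many in the wild type and few in the rescue. List length does not account for this. With 67318 top-scoring peaks in each list the share on these chromosomes was still 4.86 times higher in the wild type (4.43 to 5.34). Scores were not matched, with 7214 wild-type and 3059 rescue peaks at 100 or more in the full lists, so the lower rescue scores were not excluded. Of their 34 blocks of 10 Mb, 100% lay below the median rescue to wild-type ratio of the other autosomes and 0% reached it. Block ratios were 0.156 to 0.582, against a median of 1.47 in 220 blocks of other autosomes. Of those 220 blocks, 2 were as low, both at the end of chromosome 11 (0.173 and 0.15). The chromosomes were chosen for their few rescue peaks, which made blocks below the median likely. The deficit ran through every block and was not confined to part of either chromosome. Blocks of 10 Mb hold many peaks, so this count cannot exclude binding that differs at a limited set of sites spread along them. The same count is no separate support for copy number, but a difference in chromosome copy number between the cells and the pooled input may account for the deficit. The knockout Ezh2 list, whose control is not stated, does not decide this: chromosome 1 held 5.47% of its peaks, against 7.41% and 9.48% in wild-type libraries 0 and 1, and chromosome 8 held 8.29%, against 5.84% and 7.12%. A change in G9a binding along whole chromosomes in the rescued cells stays open and was not tested, because no input signal was analysed here. It would bear on the low rescue counts and not on the high wild-type counts.

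Ezh2 regions on chromosome X were called in the knockout in 20.0% of cases (10 of 50), against 63.4% on autosomes. Peaks were sparse on X in every list, of both proteins. Weaker wild-type peaks on X may not account for all of the difference. Autosomal regions of matched library 0 score were kept in 47.2% of cases, above the interval of 10.0 to 33.7% for X. That interval treats neighbouring regions as independent and may be too narrow, and the 47.2% has no interval. Low signal along the whole of X in the knockout library is a candidate explanation: knockout-only regions were scarce there too (4 of 1776), at 0.156 times (0.0394 to 0.284) the relative density of regions with a peak of either wild-type library. Loss of Ezh2 from X without G9a and GLP stays open, since the knockout Ezh2 signal and input along X were not measured here.

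Ezh2 regions missing from the knockout list were mostly those with low wild-type scores. Of regions in the top 10% of library 0 score 0.379% were missing, and 0% by library 1 score. A call threshold that weaker knockout signal did not pass may account for this. These values restate the pattern and were chosen after it was seen, so they are no separate support for a threshold. Library 1 peaks as a whole were less complete, with 89.97% of the top 10% found in the knockout. A general reduction of Ezh2 signal without G9a and GLP would give the same pattern as a less efficient knockout library, and the design has 1 such library. Loss at regions with a called G9a peak cannot be told apart from no such loss. The odds ratio of being kept was 1.08 (0.835 to 1.41) by score but 0.720 (0.554 to 0.929) by width. Region width includes knockout peaks, though the median span of kept regions (2992 bp) was near the median length covered by library 1 (2985 bp).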
